A study of Mus musculus with 8 samples.

How the data were processed

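Total RNA from frozen cross sections of kidney was labelled with Cy3 or Cy5 from 200 ng per mouse and hybridised to 4 two-colour Agilent arrays, per the labels' protocols. The genotype, individual number, sex and dye of each mouse were taken from the labels, which name 8 individuals, so the replicates are separate animals. Individuals with the same number and of opposite genotype shared an array and a sex. The 4 arrays lay on 1 slide and were scanned on 1 day, per the file headers, so there was no slide or scan batch to test.

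The deposited scanner files hold spot intensities per channel, made with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. They give the median signal, the median local background, a background-subtracted and dye-normalized processed signal, and flags of saturation, of outliers and of signal well above background. The authors also deposited a value table in log2 units, in which each of 55821 probes was centred on its median over the 8 mice. Its column medians were 0.00268, 0.0164, -0.017 and -0.0035 for wild-type mice 1 to 4 and 0.0106, 0.0184, -0.01 and -0.0219 for mutants 1 to 4. Each column correlates over probes with the processed signal of its own channel (0.962 to 0.981) more than with any other (at most 0.622). The direction was as labelled, and the normalization behind this table is not given in the sources used here. All columns of per-sample values were matched to a mouse.

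From the scanner files, median signals were corrected with normexp (offset 50) against the median local background and normalized within each array with loess, with control spots at weight 0. Mean signals had been planned, and median signals, the ones in the columns used here, took their place. Spots flagged as outliers in either channel were left out and replicate spots of a probe were averaged. The 3671 control spots were left out of the tests. Of 55681 probes, 27509 were named by matching RefSeq accessions without version to a gene table of assembly GRCm38.p6, for 20887 symbols. Accessions of 1641 probes were not matched and 26531 probes carried no RefSeq accession, and these were tested under their own names. The array was designed on mm9, so the table served for names and for which genes neighbour Pus1, and no coordinates are given. A probe entered the comparison of genotypes if it was well above background in all 4 mice of at least 1 genotype, and a gene was represented by its brightest such probe. This left 19968 genes and transcripts, 13427 of them with a symbol.

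The ratio of mutant over wild type within each array was fitted in limma 3.58.1 (R 4.3.3) with a genotype term and a dye term. The fit has 2 residual degrees of freedom, to which the empirical Bayes prior added 3.98. Adjusted p-values are limma's with Benjamini-Hochberg adjustment at 0.05, and errors of fitted log2 changes are standard errors. A genotype by sex term was added for the comparison of the effect between sexes, which left 1 residual degree of freedom. The sexes were compared on the 8 channel values after Aquantile normalization, with limma's separate-channel fit and the array as random block (intraspot correlation 0.149), for 21243 genes and transcripts. Where a probe was not well above background in any mouse of a sex, the fold is a lower bound. The same holds for a genotype. It sets the mean of the brighter sex against the mean, per mouse, of the higher of the dim probe's own value and the lowest value among probes well above background. With 2 mice of each sex and of each genotype in each dye, such bounds are balanced over the dyes.

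In total 53 gene lists were written before the data were examined, covering mitochondrial, tRNA modification, metabolic, stress and sex-biased genes and markers of kidney and other cell types. The 49 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Genes near Pus1 were compared with the rest by Fisher's exact test, with Pus1 left out. The genes named in the text follow a rule fixed beforehand. Since fewer than 20 genes passed, they are Pus1, every gene that passed and, as not past the threshold, the 10 genes in each direction with the smallest unadjusted p. They also include 2 to 4 members with the smallest p per described list, for genotype by sex the 6 smallest p in each direction, and for sex the 8 largest changes in each direction with the members of the sex-biased and X or Y lists. Genes without a symbol were counted but not named, and some genes that the rule takes are counted but not reported here by name. Cfd, Ucp1, Plin1 and Fabp4 were named after their values were seen.

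The pairing comes from the labels, which put both mice of a pair on 1 array. Deviations from the genotype means correlated between the mice of pairs 1 to 4 at 0.676, 0.669, 0.671 and 0.766. For 3 of the 4 wild-type mice the mutant of the same sex on the other array correlated more (0.809, 0.787 and 0.790), so these values show shared sex and do not bear on the pairing itself. The block in the comparison of genotypes, the ratio within the array, rests on the labels alone. Alternatives covered the background correction, the normalization, the filter, the dye, sex and block terms, the variance prior, the probe summary, the authors' value table and leaving out each pair.

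The fits were tested on simulated data. Over 19968 simulated genes, the genotype fit recovered 12.0% of log2 changes of 0.5, 96.0% of those of 1 and 98.0% of those of 2, with 4 false calls among 157. The genotype by sex fit over 19968 simulated genes recovered 8.00% of differences of 1 and 98.0% of those of 2, with 17 false calls among 120. The sex fit over 6000 simulated genes recovered 94.0% of changes of 0.5, with 13 false calls among 210. Every gene of the sex simulation had the same spread, whereas the real SD in females was 0.08 for Cbr1 and 1.27 for Pzp. Its recovery and false calls therefore do not carry over to the real comparison of the sexes. A list of 37 genes shifted by 0.3 over 19968 simulated genes was found by camera, with 0 false lists among the others. The simulated genes varied independently, whereas the estimated correlation within the cell cycle list was 0.724 in the real data. The 0 false lists therefore do not show how often camera calls a list falsely here.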

Results

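Kidney RNA of 8 mice was measured, 4 homozygous for a Pus1 mutation and 4 wild type, each genotype with 2 females and 2 males. Pus1 encodes a pseudouridine synthase, an enzyme that converts uridines of transfer RNA to pseudouridine in the nucleus and in mitochondria. The mice were 14 to 16 weeks old and of C57BL/6J background after 5 generations of backcrossing, and the RNA came from a cross section of the whole kidney. Each of 4 two-colour arrays held 1 mutant and 1 wild-type mouse of the same sex, called a pair here. Pairs 1 and 2 were female and pairs 3 and 4 male, and the dyes were exchanged in pairs 2 and 4. Between 48.3% and 54.8% of the probes lay well above background in each mouse. Between 15 and 20 spots were saturated in each Cy5 channel and 0 in each Cy3 channel. The number of arrays limits the precision.

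The first comparison asked which transcripts differed between mutant and wild-type kidneys. Pus1 itself was 7.77-fold lower in mutants (log2 change -2.96, SE 0.07, 4 pairs; limma adjusted p = 0.000338). Its log2 level was 10.27 ± 0.18 (SD, n = 4) in wild-type and 7.31 ± 0.27 (SD, n = 4) in mutant kidneys, with no overlap, and its probe stayed well above background in all 4 mutants. The pairs gave log2 ratios of -2.93, -2.85, -3.09 and -2.98. Whether the probe lies within the altered part of the gene is not stated, so the residual signal is not a measure of functional transcript. Besides Pus1, the genes that passed included 4 with values as follows. Hsd17b11, a hydroxysteroid dehydrogenase found on lipid droplets, was 2.21-fold higher, and the clone-named gene 1500011B03Rik was 2.71-fold higher. Stbd1, a glycogen-binding protein, was 2.35-fold lower, and the neuropeptide Y receptor gene Npy6r was at least 1.84-fold lower, since its probe was not well above background in any mutant.

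All 4 had the same direction in all 4 pairs, and of all named genes only Pus1 passed in every fit without 1 pair. The log2 change was 1.14 (SE 0.07) for Hsd17b11, with an adjusted p of 0.0179 from limma, and 1.44 (SE 0.07) for 1500011B03Rik, with an adjusted p of 0.00694. A second probe of 1500011B03Rik gave a mean log2 ratio of -0.02, so the 2 probes of this gene disagreed. The fall of Npy6r had an adjusted p of 0.0460 from limma, and it did not pass with processed signals or without background correction (limma adjusted p = 0.0649 and 0.107). Stbd1 changed by -1.23 (SE 0.08; limma adjusted p = 0.0211), but its ratios were -0.40 and -0.46 where the mutant was labelled with Cy5 and -1.88 and -2.19 where it was labelled with Cy3. In all, 8 of 19968 genes and transcripts passed, 2 higher and 6 lower, of which 2 lower ones had no gene symbol. At an unadjusted p under 0.05, limma gave 929, against 998 from chance alone.

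The genes with the next smallest p did not pass the threshold. On the higher side, log2 changes of 0.83 (SE 0.08) for Clic6, a chloride channel family member, 0.79 (SE 0.08) for Vps33a, a vesicle sorting protein, and 0.80 (SE 0.08) for the histone demethylase gene Kdm2b each had a limma adjusted p of 0.115. Dividing-cell genes were among the others, with 0.64 (SE 0.08) for the ribonucleotide reductase subunit gene Rrm2, 0.71 (SE 0.10) for Cdc20, an activator of the anaphase-promoting complex, and 0.53 (SE 0.07) for the mitotic kinase gene Pbk. The values were 0.55 (SE 0.07) for Cds1, a phospholipid synthesis enzyme, 0.78 (SE 0.10) for Cyp26b1, which degrades retinoic acid, 0.64 (SE 0.08) for the apolipoprotein gene Apom and 0.57 (SE 0.08) for Rita1. On the lower side, the log2 change was -0.82 (SE 0.10) for P2rx7, an ATP-gated channel, and -0.50 (SE 0.07) for Hscb, a cochaperone of iron-sulfur cluster assembly. A second kept probe of P2rx7 gave 0.16, in the other direction. It was -0.75 (SE 0.11) for Azgp1, -0.48 (SE 0.07) for the cofilin phosphatase gene Ssh1, and -0.48 (SE 0.08) for Nap1l5. The dynein light chain gene Dynll1, whose probe was not well above background in any mutant, was at least 1.47-fold lower. The log2 change was -0.48 (SE 0.08) for Aacs, which activates acetoacetate, -0.46 (SE 0.08) for Rflna, -0.40 (SE 0.07) for 2010109A12Rik and -0.38 (SE 0.07) for Tesc. As for Stbd1, the ratios of several of these genes parted by dye orientation, and the widest gaps are given here, first for the mutant labelled with Cy5 and then with Cy3. They were 0.18 and 0.25 against 0.89 and 1.23 for Apom, 0.31 and 0.17 against 1.00 and 0.79 for Rita1, -0.11 and -0.11 against -0.74 and -0.65 for 2010109A12Rik, and 0.86 and 1.33 against 0.55 and 0.39 for Cyp26b1. The probes of Ssh1 and 2010109A12Rik were well above background in 1 of the 4 mutants, and that of Pbk in 1 of the 4 wild-type mice. The log2 changes of Ssh1, 2010109A12Rik and Pbk thus lie near background and are less sure. Without pair 1, 2, 3 or 4, limma called 1, 4, 1 and 5 genes. The authors' value table gave 0 genes in limma, with 1017 at an unadjusted p under 0.05, and Agilent's processed signals gave 1, Pus1.

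**Figure D1:**
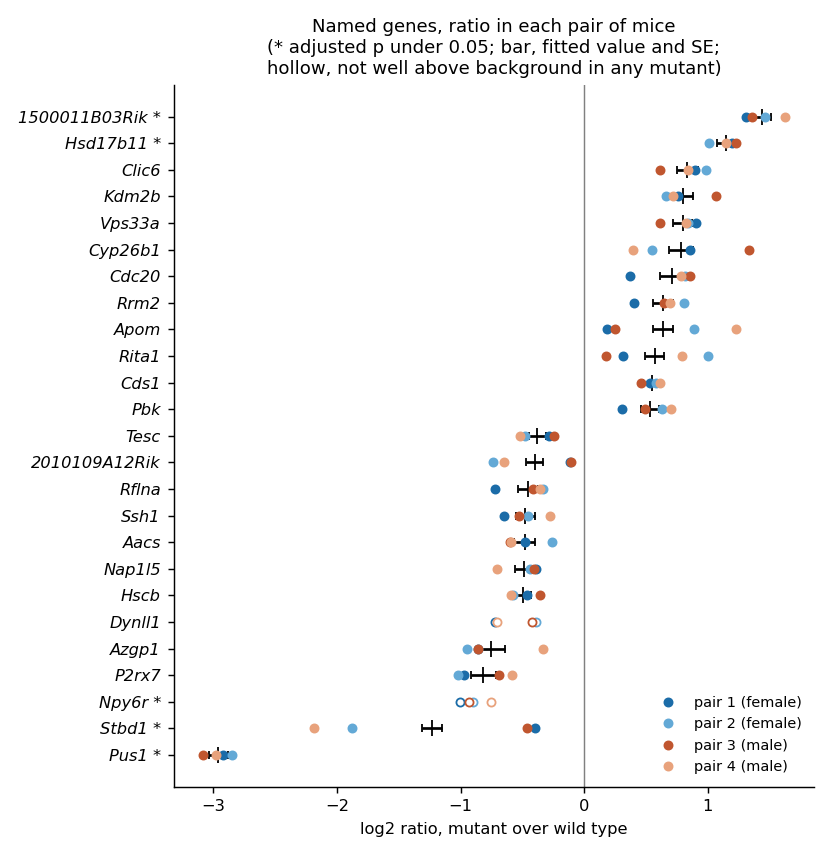
Each row is a gene named for the comparison of genotypes and the horizontal axis is the log2 ratio of mutant over wild type. Dots are the 4 pairs of mice and the bar is the fitted value with its SE. Hollow dots without a bar mark Npy6r and Dynll1, whose probes were not well above background in any mutant. Pus1 lies near -2.96 in all 4 pairs, while the dots of Stbd1 part by dye orientation from -0.40 to -2.19.

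The mice had been backcrossed for 5 generations, so the position of the changed genes relative to Pus1 on chromosome 5 was examined. Of the genes described above, Hsd17b11, 1500011B03Rik and Stbd1 lie within 20 Mb of Pus1 and Npy6r lies on chromosome 18. Within 20 Mb, 4 of 300 tested genes passed, against 1 of 13126 elsewhere (odds ratio 177, two-sided Fisher's exact p = 1.2e-06). At an unadjusted p under 0.01, 36 of the 300 genes (12%) were counted against 103 of 13126 (0.785%; odds ratio 17.2, two-sided Fisher's exact p = 1.54e-28). Of those 36 genes, 20 were higher and 16 lower in mutants. Among them are Vps33a, Kdm2b, Cds1 and Rita1, which were higher, and P2rx7, Hscb, Ssh1, Dynll1, 2010109A12Rik, Aacs, Rflna and Tesc, which were lower, none of them past the adjusted threshold. The share was 12% within 2 Mb, 12.3% between 2 and 10 Mb, 11.7% between 10 and 20 Mb and 1.92% between 20 and 40 Mb. Without pair 1 or pair 3, no named gene besides Pus1 passed, so the test could not be made there. Fisher's test counts genes as independent, although all were measured in the same 4 pairs, so its p-values do not measure variation between mice.

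**Figure D2:**
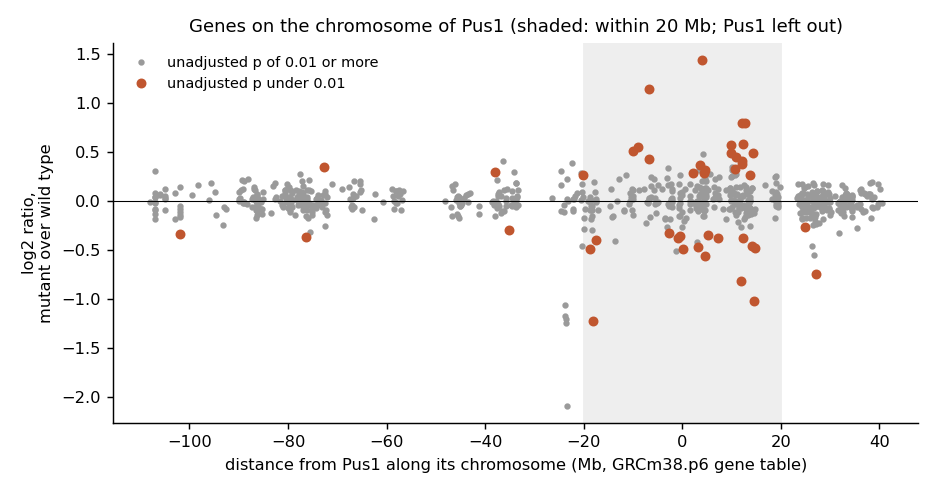
Each dot is a tested gene on the chromosome of Pus1, placed by its distance from Pus1 in Mb on the horizontal axis and by its log2 ratio of mutant over wild type on the vertical axis. The shaded span of 20 Mb to either side holds 36 genes with an unadjusted p under 0.01, of which 20 lie above and 16 below 0.

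Groups of genes fixed beforehand were compared between genotypes with camera, and 15 of 49 lists passed, 10 higher and 5 lower in mutants. Cell cycle genes stood first. All 20 measured members had a positive log2 change (median 0.36; camera adjusted p = 4.77e-18, and adjusted p = 0.882 with an estimated correlation). None of the 20 passed over all genes tested and 12 passed adjusted over the list alone, among them Rrm2 (0.64, SE 0.08), Cdc20 (0.71, SE 0.10), Birc5 (0.68, SE 0.10) and Cdk1 (0.42, SE 0.08). The median ratio of the list was 0.06, 0.49, 0.60 and 0.39 in the 4 pairs. Of the 15 lists, 4 passed in camera without each pair in turn, namely cell cycle, distal tubule, complex I and glycolysis genes, and the other 11 no longer passed without at least 1 pair. With an estimated correlation 0 of the 49 lists passed in camera, and 0 had an unadjusted p under 0.05. The directional fry test passed 0 of 49 lists, with 2 at an unadjusted p under 0.05.

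Lists of nephron segment markers moved in both directions. Of 13 distal tubule markers 11 had a positive log2 change (median 0.19; camera adjusted p = 8.71e-07, and 0.882 as adjusted p with an estimated correlation), led by Calb1 (0.52, SE 0.13) and S100g (0.35, SE 0.09), which bind calcium. Of 13 loop of Henle markers 10 were above 0 (median 0.10; camera adjusted p = 0.00305), and 4 passed adjusted over the list alone. These were Ptger3 (0.51, SE 0.09), Umod (0.29, SE 0.07), Egf (0.35, SE 0.10) and the cotransporter gene Slc12a1 (0.30, SE 0.09). Intercalated cell markers were lower (11 of 15 below 0, median -0.06; camera adjusted p = 0.0356), with Kit at -0.30 (SE 0.07) and Aqp6 at -0.21 (SE 0.07). The adjusted p of the loop and intercalated lists was 0.882 with an estimated correlation, and neither passed without pair 2 or without pair 3. The intercalated list also did not pass with median centring in place of loess (camera adjusted p = 0.0528). No distal tubule or intercalated member passed adjusted over its list alone. Principal cell markers of the collecting duct, 8 of 11 below 0, did not pass (median -0.10; camera adjusted p = 0.165). Markers of inner medulla did not pass (camera adjusted p = 0.380), but their median ratio moved between pairs, with -1.45, -1.19, 1.39 and -0.10.

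Of 4 lists of respiratory chain genes encoded in the nucleus, 3 passed, with small positive medians, and complex IV did not (13 of 17 above 0, median 0.06; camera adjusted p = 0.0759). With all genes within 20 Mb of Pus1 left out, an alternative chosen after seeing the data, complex IV passed as well (camera adjusted p = 0.0310). Complex I members were above 0 in 34 of 37 cases (median 0.07; camera adjusted p = 2.81e-06), with Ndufab1 at 0.24 (SE 0.07) and Ndufa11 at 0.22 (SE 0.07). The complex I median was 0.13, 0.04, -0.04 and 0.14 in pairs 1 to 4, so it was not above 0 in pair 3. All 15 complex V members were above 0 (median 0.11; camera adjusted p = 0.000259), with Atp5k, which lies within 20 Mb of Pus1, at 0.17 (SE 0.07) and Atp5a1 at 0.21 (SE 0.09). The complex V median was 0.27 in pair 1 and between -0.02 and 0.05 in the other pairs, and the list did not pass without pair 1 (camera adjusted p = 0.163). Of the members of complexes II and III, 12 of 14 were above 0 (median 0.09; camera adjusted p = 0.00632), with Cyc1 at 0.19 (SE 0.07) and Uqcrc1 at 0.17 (SE 0.07). This list did not pass without pair 1 or pair 4 (camera adjusted p = 0.359 and 0.157) or with median centring in place of loess (camera adjusted p = 0.0820). Glycolysis genes were above 0 in 15 of 18 cases (median 0.08; camera adjusted p = 0.000731), with Pgk1 at 0.24 (SE 0.08) and Pkm at 0.24 (SE 0.09). The adjusted p of each of the 4 lists that passed here was 0.882 with an estimated correlation, and no member passed over all genes tested or adjusted over the list alone. Other pseudouridine synthases did not follow Pus1. Of 12 measured, Pus1 alone passed, and the next smallest p belonged to Trub2 (0.13, SE 0.07) and Rpusd4 (0.13, SE 0.08). Mitochondrial ribosomal proteins (median 0.02; camera adjusted p = 0.165), mitochondrial tRNA processing genes (median 0.02; camera adjusted p = 0.597) did not pass, nor did the integrated stress response, with 11 of 22 members above 0. Transcripts of the mitochondrial genome had no named probe and were not analysed here.

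Cholesterol and fatty acid synthesis genes were above 0 in 22 of 27 cases (median 0.18; camera adjusted p = 0.000128), led by Mvk (0.37, SE 0.07), the 1 member to pass adjusted over the list alone, and Cyp51 (0.30, SE 0.09). Mvk lies within 20 Mb of Pus1, and the list did not pass without pair 4 (camera adjusted p = 0.152). Interferon response genes were above 0 in 20 of 25 cases (median 0.16; camera adjusted p = 1.2e-05), with Oas2 at 0.49 (SE 0.12) and Oasl2 at 0.48 (SE 0.14), although the median of pair 4 was -0.13. Oas2 and Oasl2 are among 6 members that lie within 20 Mb of Pus1, so their changes cannot be told apart from those of the region. The other 19 members passed as a list with the genes near Pus1 left out (camera adjusted p = 0.000101). The interferon list did not pass without pair 2 or pair 3 (camera adjusted p = 0.178 and 0.0755). Macrophage markers were above 0 in 10 of 13 cases (median 0.09; camera adjusted p = 0.0164), with Adgre1 at 0.38 (SE 0.11) and Lyz2 at 0.36 (SE 0.11). Their median was 0.28 in pair 2 and 0.15 in pair 4 but below 0 in pairs 1 and 3, and the list did not pass without pair 2 or pair 3 (camera adjusted p = 0.189 and 0.124). Neutrophil markers did not pass as a list (2 of 5 above 0, median -0.05; camera adjusted p = 0.250), but S100a8 (0.58, SE 0.13) and S100a9 (0.57, SE 0.14) passed adjusted over the list alone. The lower lists included erythroid genes, of which 11 of 12 were below 0 (median -0.24; camera adjusted p = 0.000979). Among them were the globin genes Hba-a2 (-0.38, SE 0.08), which passed adjusted over the list alone, and Hbb-bt (-0.39, SE 0.17). The erythroid median was -0.77 in pair 2 and between -0.06 and -0.01 in the other pairs, and the list did not pass without pair 2 (camera adjusted p = 0.289). Cytosolic ribosomal proteins (61 of 75 below 0, median -0.04; camera adjusted p = 0.00305) were led by Rpl15 (-0.19, SE 0.07) and Rps25 (-0.16, SE 0.07), and did not pass without pair 1 or pair 2 (camera adjusted p = 0.143 and 0.324). Immediate early genes (14 of 17 below 0, median -0.14; camera adjusted p = 0.00517) were led by Fosb (-0.24, SE 0.07) and Jund (-0.22, SE 0.08). Their median was -0.37, -0.13, 0.06 and 0.01 in the 4 pairs, and the list did not pass without pair 1 or pair 2 (camera adjusted p = 0.909 and 0.0824). Circadian clock genes (13 of 17 below 0, median -0.14; camera adjusted p = 0.0342) were led by Nr1d1 (-0.17, SE 0.08) and Dbp (-0.27, SE 0.14), and their direction turned without pair 2, while without pair 3 or with processed signals they did not pass (camera adjusted p = 0.386 and 0.0555). With all members, the adjusted p of each list in this paragraph that passed was 0.882 with an estimated correlation.

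**Figure D3:**
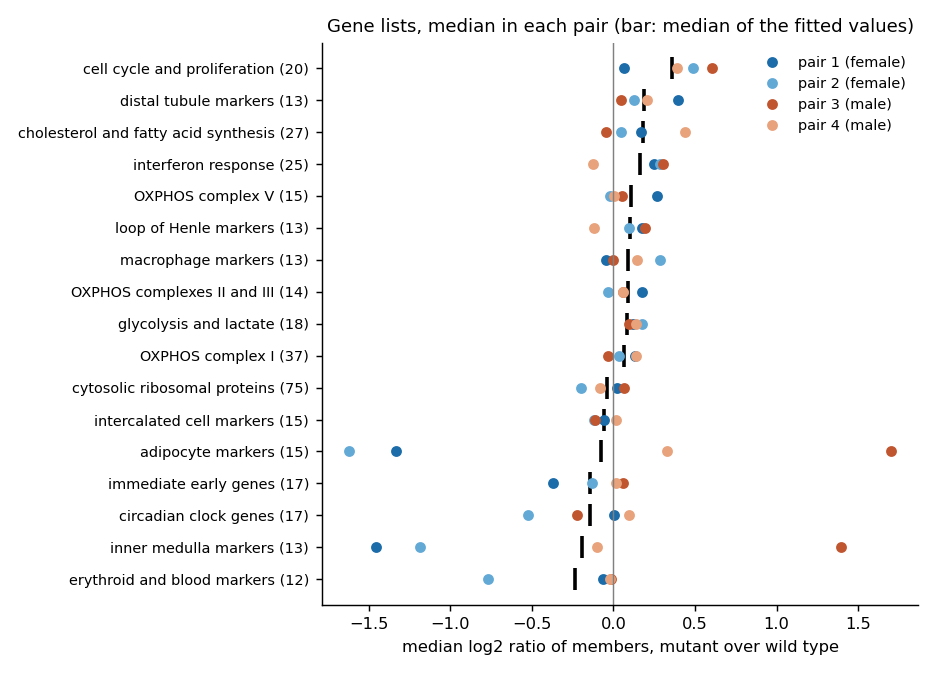
Each row is a gene list, with its number of measured members, and the horizontal axis is the median log2 ratio of mutant over wild type of its members. Dots are the 4 pairs and the bar is the median of the fitted values. Cell cycle genes have a median of 0.36, the erythroid median is lowest in pair 2 at -0.77, and the adipocyte and inner medulla markers range over the pairs from -1.62 to 1.70.

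The genotype effect was then compared between females and males. It differed for 27 of 19968 genes and transcripts, and in each the mutant over wild-type ratio was lower in females. The 6 with the smallest p were the major urinary protein genes Mup19, Mup17 and Mup18, Apoc1, an apolipoprotein, Hp, which encodes haptoglobin, and Adrb3, the beta-3 adrenergic receptor of adipocytes. The female minus male difference in log2 was -4.20 (SE 0.22) for Mup19, -4.04 (SE 0.23) for Mup17, -4.25 (SE 0.28) for Mup18, -3.20 (SE 0.20) for Apoc1, -2.87 (SE 0.18) for Hp and -2.46 (SE 0.17) for Adrb3. The limma adjusted p lay between 0.00727 and 0.00808 for these 6. The Mup genes are close copies of each other, so their probes cannot be taken as separate genes. The ratio of Mup19 was -0.25, -3.70, 3.61 and 0.84 in the 4 pairs. Pairs of the same sex also differ in dye orientation, so the dye term took up most of this spread within each sex. The ratios of Apoc1 (-0.52, -2.32, 2.41 and 1.16) and Hp (-0.86, -2.30, 1.83 and 0.75) parted in the same way. For every gene of this fit, the dye term takes up the gap between pairs that is common to both sexes. The SE and adjusted p, above all of the Mup genes, Apoc1 and Hp, therefore do not measure the spread between mice. For Adrb3 the log2 ratio was -1.44 (SE 0.12) in females, and the pairs gave -1.38, -1.49, 1.12 and 0.93. Genes on the list of adipocyte markers made up 8 of the 27 genes. Among these 8 were Cfd (-3.33, SE 0.34), Ucp1 (-4.44, SE 0.45), Plin1 (-3.04, SE 0.33) and Fabp4 (-2.61, SE 0.25). Over the 15 adipocyte markers measured, the median ratio was -1.33 and -1.62 in the female pairs and 1.70 and 0.33 in the male pairs. The median female minus male difference was -2.81 for adipocyte, -1.87 for inner medulla, -0.40 for hepatocyte and 0.06 for proximal tubule markers.

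In the other direction no gene passed. The 6 genes with the smallest p were Igf2os (0.95, SE 0.17), Spidr (0.85, SE 0.17), Aqp8 (0.92, SE 0.20), Hdc (0.84, SE 0.19), Bdnf (0.90, SE 0.21) and Prps2 (0.80, SE 0.19), with a limma adjusted p of 0.251 or more. With genotype tested within each sex, limma called 32 genes in females, 3 higher and 29 lower, and 10 in males, 7 higher and 3 lower. The 27 genes rested on the dye term, since the same limma fit without it called 0, with 305 at an unadjusted p under 0.05. Leaving out a pair meant leaving out the dye term too, so these fits do not show what a single pair adds to the 27. On the 3 remaining arrays, 0 genes passed in limma without pair 1 or pair 2 (622 and 451 at an unadjusted p under 0.05), 1 without pair 3 and 91 without pair 4.

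Females and males differed widely, whatever their genotype. The amino acid transporter gene Slc7a13 was well above background in all 4 males and in no female, and was at least 243-fold higher in males. Acsm3, a medium-chain acyl-CoA synthetase, was 46.8-fold higher (log2 5.55, SE 0.31), Cyp7b1, an oxysterol hydroxylase, 42.3-fold higher (5.40, SE 0.20), and Pzp, a protease inhibitor, 21.6-fold higher (4.43, SE 0.47). Pnma2 (4.31, SE 0.18) and Cmya5 (4.29, SE 0.17) were also among the 8 largest. Of these male-higher genes only Acsm3 had a second kept probe, which gave 5.54, and the others each rested on 1 kept probe. Higher in females were Hdc, the histidine decarboxylase gene (26.8-fold; -4.74, SE 0.21), the transporter genes Abcc3 (21.3-fold), Slc7a12 (16.8-fold), Slc22a29 (12.8-fold) and Slc17a2 (well above background in all 4 females and in no male), the protease gene Tmprss6 (20.8-fold) and Cbr1, a carbonyl reductase (9.90-fold). Hdc was well above background in 2 and Tmprss6 in 1 of the 4 males. A second kept probe of Slc17a2 gave -2.26, and the other genes named here as higher in females each rested on 1 kept probe. The limma adjusted p was between 3.28e-07 and 0.000337 for the genes of this paragraph.

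Genes used to check the labels followed sex. Eif2s3y and Ddx3y, on the Y chromosome, were well above background only in the 4 males, at least 32.5-fold and at least 16.1-fold higher, and Xist, which silences an X chromosome, only in the 4 females, at least 9.19-fold higher, although a second kept probe of Xist gave a log2 difference of -1.27. The Y gene Uty was well above background in 4 males and in 2 females and did not differ (0.18, SE 0.45; limma adjusted p = 0.759). Kdm6a (-1.03, SE 0.10) and Ddx3x (-0.53, SE 0.09), on the X chromosome, were lower in males, and Kdm5c (-0.14, SE 0.08) did not pass. Second probes gave -0.02 for Ddx3x and -0.45 for Kdm5c. The probe used for Eif2s3x gave 1.64 (SE 0.07), higher in males, while a second probe of it gave -0.43.

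Of 15 measured genes listed beforehand as male-biased, 13 were higher in males, among them Cyp4a12a (3.77, SE 0.15), Cyp4a12b (3.68, SE 0.15), Cyp4b1 (3.18, SE 0.12), Cyp2e1 (2.82, SE 0.21), Ugt8a (2.33, SE 0.19), Cyp2d9 (1.96, SE 0.12), Hsd17b11 (1.95, SE 0.15), Odc1 (1.17, SE 0.25) and Cyp2j13 (0.83, SE 0.12). Slco1a1 was at least 9.13-fold higher in males. For Cyp2j13, 2 other kept probes gave 3.34 and 4.49. The exceptions to the list were Abcc3, higher in females, and Kap, which encodes an androgen-regulated kidney protein (-0.04, SE 0.09). The Kap spot was saturated in 4 of the 8 mice, 2 of each sex, so a difference may be compressed and its absence is not firm. Of 13 genes listed as female-biased, 9 were higher in females, among them Prlr (-2.59, SE 0.20), Gsta4 (-2.22, SE 0.11), Cyp4a14 (-1.85, SE 0.49), Abcc4 (-1.55, SE 0.15), Napsa (-1.21, SE 0.09), Cyp2d12 (-0.47, SE 0.15) and Slc22a7 (-0.37, SE 0.11). Rnf24 (1.24, SE 0.29) and Cyp2a4 (0.67, SE 0.16) were higher in males, and Sult1d1 (-0.19, SE 0.14) and Corin (0.13, SE 0.13) did not pass.

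Over all genes and transcripts, 10740 of 21243 differed between the sexes in limma's separate-channel fit, 4319 higher and 6421 lower in males. At a difference of at least 2-fold the order turned, with 1275 higher and 322 lower in males. Where a gene at least 2-fold higher in males had another kept probe, 33.8% of the 148 other probes showed at least 0.5 of the log2 change in the same direction, against 58.3% of 60 for genes higher in females. Each sex lay on 2 arrays of 1 slide, so the sexes differ between arrays as well. Without pair 1 or pair 2 the count was 6604 or 6395.

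**Figure D4:**
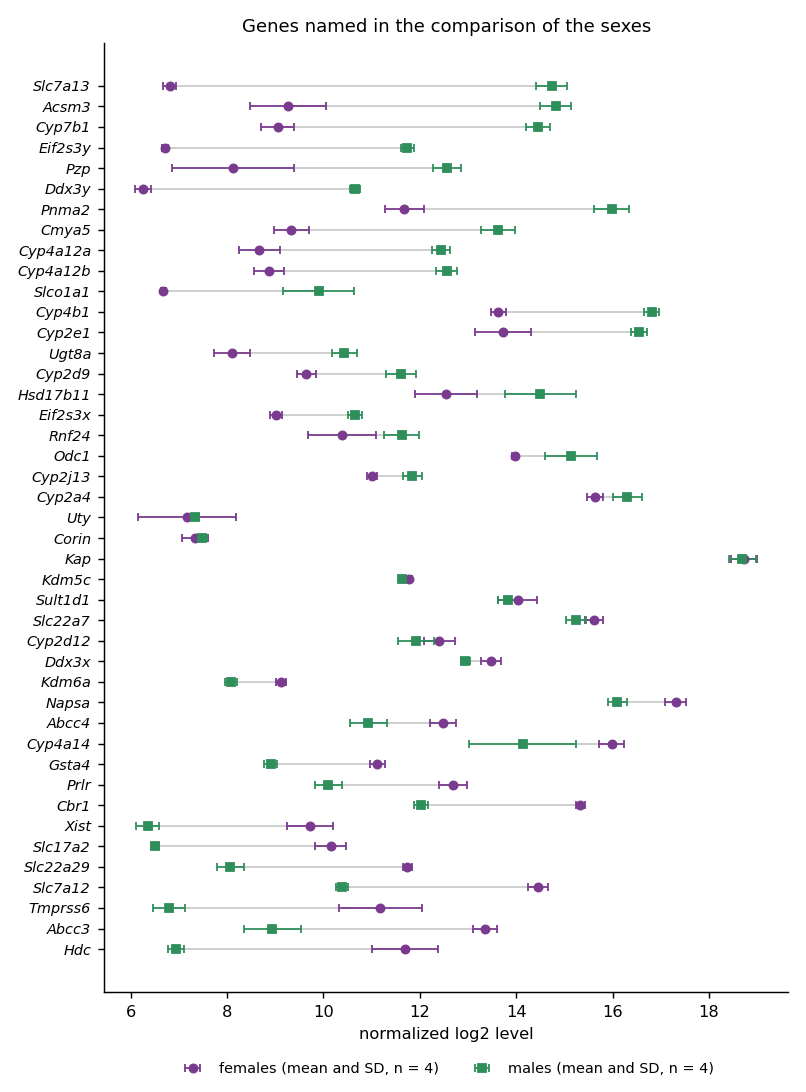
Each row is a gene named for the comparison of the sexes and the horizontal axis is its normalized log2 level. Points and bars are the mean and SD of the 4 females and the 4 males. Slc7a13 at the top has means of 6.81 in females, where it was not well above background, and 14.73 in males, and Hdc at the bottom 11.69 and 6.95.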

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

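The tests of marker lists in this part were chosen after the results were seen, and the comparison with other splits of the arrays was planned.

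In 41 sets of 4 pairs, 5 had 1 pair far from the others, where chance would give about 2.05 for independent sets. These sets include genes chosen by their p and medians of lists, all on the same 4 arrays, so that figure does not hold for them. The log2 ratio of Cdc20 was 0.37 in pair 1, that of Azgp1 was -0.33 in pair 4 and that of Nap1l5 was -0.70 in pair 4, each apart from the other 3 pairs. The median of the interferon response list was -0.13 in pair 4 and positive in the others, and the erythroid median was -0.77 in pair 2.

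The genotype effect differed between females and males for 27 genes by the interaction term of limma, all lower in females, including Mup19 (-4.20), Mup17 (-4.04), Apoc1 (-3.20), Hp (-2.87), Mup18 (-4.25) and Adrb3 (-2.46). Adipocyte markers, of which 15 of 17 were measured in these kidneys, had a median female minus male difference of -2.81, which none of 10000 random lists of like size and brightness reached. None reached the medians of inner medulla (-1.87), hepatocyte (-0.40) or erythroid markers (-0.38) either, whereas 0.770% were as far from 0 as female-biased kidney genes (-0.14), 10.5% as skeletal muscle and 19.5% as adrenal markers. The random lists drew genes independently, while the adipocyte markers moved together (estimated correlation 0.79). These shares therefore do not measure variation between mice, and the erythroid median was far from 0 in pair 2 only. In addition, 8 of the 15 adipocyte markers were among the 27 genes that prompted the test. The ratio of the abundant fat transcript Cfd was -2.11, -2.49, 1.98 and 0.09 in pairs 1 to 4, whereas that of Mup19 was -0.25, -3.70, 3.61 and 0.84, a different pattern. Different amounts of fat in the pieces of kidney, which were whole cross sections with no sort, may account for the 8 listed adipocyte markers among the 27 genes. The count of 8 covers only genes on that list. Outside it, the adipocyte receptor gene Adrb3 had ratios of -1.38, -1.49, 1.12 and 0.93, against -1.56, -1.59, 2.21 and 0.72 for Plin1. How many more of the 27 go with fat was not tested. Of the 27, 0 are inner medulla markers, but 12 of the 13 measured inner medulla markers had a lower ratio in females. Different shares of inner medulla in the pieces thus stay open too. The Mup genes, Apoc1 and Hp are left open, as is an action of the mutation that differs between the sexes, which was not tested apart from shares of tissue. The other split of the 4 arrays that could be fitted gave 0 genes against the real 27, so the real one alone, 1 of 2, gave as many, and 2 splits are too few for a share under 0.05. In the other split the real difference between the sexes becomes the residual error. Its 0 was thus close to fixed in advance and does not show what chance gives.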

How the results depend on the processing

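The alternatives were planned, except the fit with the adipocyte ratio as a covariate, the lists with genes near Pus1 left out, the authors' table for genotype by sex and its fits without a pair, which were chosen after seeing the data. The log2 change of Pus1 lay between -3.88 and -2.79 in every alternative and passed in all but the authors' value table (-3.88, limma adjusted p = 0.0903). The count of 8 genes became 1 with processed signals, 4 without the dye term, 13 with a robust and trended prior, 5 with the mean of all probes and 0 with the authors' value table (limma, 1017 at an unadjusted p under 0.05). It ranged from 1 to 5 when 1 pair was left out, and was 10, 4 higher and 6 lower, with median centring in place of loess. Without the replicate block, on channel values as 8 independent samples, it was 8, of which 5 were shared with the paired fit, and the list count was 17. The block changed the calls of Hsd17b11 and Stbd1, which passed in the paired fit and not without the block, and of Vps33a and Kdm2b, which did the reverse, and of no other gene named here. Vps33a and Kdm2b also passed in the paired fit with a robust and trended prior, and Vps33a with median centring. With the adipocyte ratio as a covariate it was 6, of which 5 were shared. No named gene changed direction in any alternative. Among their values besides Pus1, 489 kept their side of the threshold, 62 no longer passed and 10 newly passed. The 27 genes with a sex-dependent effect became 0 with processed signals (875 at an unadjusted p under 0.05), 193 with median centring, 66 without the filter, 0 without the dye term (305) and 0 with the authors' table (842), and ranged from 0 to 91 in fits without 1 pair, which also had no dye term, so the pair and the dye term cannot be told apart there. The 15 lists became 16 with genes near Pus1 left out, between 12 and 21 without 1 pair, where 11 of the 15 lost their call at least once, 0 with an estimated correlation (0 of 49 at an unadjusted p under 0.05) and 0 with fry (2 at an unadjusted p under 0.05). The sex count ranged from 6395 to 8657 without 1 pair, with the intraspot correlation held at that of all 4 arrays and a lone array of a sex assumed to vary like the others. The share of changed genes near Pus1 kept its call in each alternative that gave one, and processed signals and leaving out pair 1 or pair 3 left no named gene to test. The cause of these shifts was not tested, except that leaving out a pair leaves 3 arrays. Between 48.3% and 54.8% of the probes were well above background in a mouse, and dimmer genes were tested only in the fits without the filter, where 37018 genes and transcripts gave 8 changed between genotypes.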

Other observations

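Tests of the strain, neighbour and probe mismatch explanations were chosen after the gathering near Pus1 had been seen. The test of other probes in the comparison of the sexes and the comparisons with other splits of the mice were planned.

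Besides the sex-biased genes, counts for some lists, chosen after they were seen, are set here beside all genes and transcripts, of which 6421 of 21243 were higher in females in limma's separate-channel fit. Cytosolic ribosomal proteins were higher in females in 58 of 75 cases and in males in 1, with a median male minus female log2 difference of -0.39. Members of complex I were higher in females in 24 of 37 cases (median -0.26) and members of complex IV in 12 of 17 (median -0.35). Antigen presentation genes of MHC class II were higher in females in 11 of 14 cases (median -0.69), lymphocyte markers in 8 of 11 (median -0.42), podocyte markers in 7 of 11 (median -0.51) and immediate early genes in 10 of 17 (median -0.50). These lists were not tested as sets for sex, so the counts do not show that a list differs from the other genes.

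Just outside the span of 20 Mb around Pus1, 5 genes of the Ugt2b family of glucuronosyltransferases, chosen after their values were seen, split by pair and not by genotype alone. The mutant over wild-type log2 ratio of Ugt2b38 was -0.23, -5.02, -2.99 and -0.12 in pairs 1 to 4 and that of Ugt2b5 was -0.25, -2.80, -1.84 and 0.04, and neither passed in limma (-2.09, SE 0.82 and -1.21, SE 0.48). These genes are close copies, so their probes are not separate measures.

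Genes that differed between genotypes gathered around Pus1, where 12% of the genes within 20 Mb had an unadjusted p under 0.01, and the highest share in 199 other windows of the same width was 3.00%. An effect of the targeted allele on its closest neighbours alone does not account for this, since genes between 2 and 20 Mb still had an odds ratio of 17.2 (95% interval 11.0 to 26.3). Probes that bind another strain's sequence less well would lower the mutant signal, yet 55.6% of the 36 genes were higher in mutants (exact 95% interval 38.1 to 72.1), so mismatch does not account for those. For the lower genes it cannot be told apart, with 50% of only 2 other probes following. A candidate explanation, as a hypothesis, is DNA of another strain that stayed linked to Pus1 through the 5 backcrosses and changes the expression of its own genes, although the share of 12% only shows that this region stands apart.

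Genes at least 2-fold higher in males outnumbered those higher in females by 1275 to 322. If an abundant male RNA bound unrelated probes, other probes of the same genes would follow less often, and 33.8% of 148 did against 58.3% of 60 for genes higher in females (two-sided Fisher's exact p = 0.00172). Above 4-fold the shares were 29.5% of 61 and 88.9% of 9. Binding of male RNA to unrelated probes may thus account for part of the male excess, while genes with 1 kept probe, such as Pnma2 and Cmya5, could not be tested this way. Other probes can also measure other transcripts of a gene, which was not tested, and a larger true response in males stays open.

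Splits of the mice within pairs could be fitted for 7 of 8 patterns of exchange, which is too few for a share under 0.05. For genotype the real split gave 8 genes and the highest other 11, so that 2 of the 7 gave as many. That other split exchanged both male pairs and thus follows the difference between the sexes described with the fat markers. For the gene lists the real split gave 15 and the highest other 20, and 6 of the 7 gave as many. Near Pus1 the real split gave 4 genes and every other fitted split 0, so 1 of the 7 gave as many, but 5 of the 6 others called 0 genes anywhere, and for them a 0 near Pus1 was certain. At an unadjusted p under 0.01, the real split gave 36 genes within 20 Mb of Pus1 and the others between 0 and 6. For sex, both mice of an array are alike, and only 3 splits keep the arrays whole, which is too few for a share under 0.05. The real one gave 10740 genes, 1 of the 3, and the other 2 gave 0 in limma (17 and 12 at an unadjusted p under 0.05). Those 2 splits leave the difference between the sexes in the variation between arrays, with an intraspot correlation of 0.80 against 0.149. Their 0 was therefore close to certain and does not show what chance gives.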
